A study of Mus musculus with 10 samples.

How the data were processed

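Unless said otherwise, values come from the deposited matrix of expected counts, which the authors made with alevin, part of Salmon 1.2.0, against the mouse genome GRCm38 (mm10), by the submitters' processing notes. Expected counts divide reads that fit more than 1 gene among these genes, so 87.2% of stored values were whole and the rest fractions. The deposited log2 matrix was made by the authors from these counts; in each cell it equals the log2 of the count divided by 1 factor per cell, plus 1. It served as an alternative only. Seurat is named in the submitters' processing notes for later steps. The parameters of barcode filtering, the annotation behind the counts, the clustering and the marker genes behind the class names are not given in the sources used here. Libraries were made with the 10x Chromium 3' version 2 kit and read on a NextSeq 500, per the labels. The genes of cytosolic ribosomal proteins were missing from the deposited table apart from 16 with such names, and the reason is not given in the sources used here.

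The tables held 22135 genes, of which 17634 had a count. All 35350 deposited cells were kept. Each had at least 1201 genes and under 22% mitochondrial counts, so the deposit had already been filtered, and no filter was added here. Background RNA in droplets was not estimated, because the deposit holds no empty droplets, so low levels of a gene in a class may come from other cells. Class names are those of the authors. Gene identifiers were matched to GENCODE M21 on GRCm38 for positions and transcript lengths, and a length was found for 12250 of 12257 tested genes. Of the symbols, 23 stand for 2 or more identifiers. Genes of near-identical families, such as the defensins (Defa), histones (Hist1h2ap), Reg1, Ly6a, Gsta1 and Sprr2a3, share reads with relatives, and so does Ndufb1-ps, which carries a pseudogene symbol. Their values may hold counts of those relatives.

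For trends, counts were summed over the cells of each library and rounded after summing. The unit of replication was the library, with 9 libraries from 24 to 108 h. Genes were kept by edgeR's filterByExpr with a minimum count of 10, scaled by TMM, and fitted with edgeR's quasi-likelihood test on a slope of hours, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a limit of 0.05. Changes are the slope times 84 h, with the SE from the same fit. A second model added the square of hours, and its value is the fitted level at 66 h less the mean of the levels at 24 and 108 h. The same linear test ran within each of the 5 classes with at least 50 cells in 7 or more libraries. Differences of slope between a class and the TA and stem cell progenitors were tested as an interaction term over the libraries both classes had. Because the 36 h pair is the only repeat, the residual degrees of freedom come mainly from scatter about the line.

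Gene lists (36) were written from general knowledge before the files were opened. Those with at least 3 measured genes (32) were tested by camera of limma with an inter-gene correlation preset at 0.01 and again with a correlation estimated per list. Counts of risen and fallen members are given with adjustment over all genes and with adjustment over the list alone. The genes named in the text follow a rule set beforehand. For trends these were the 10 rising and 10 falling genes with the largest slope among those that passed, with a mean of at least 20 CPM and the same sign with each library left out, plus up to 3 members of each list with the highest mean. For the quadratic term these were 8 on each side, within classes 5 on each side, and for single libraries 10 on each side with at least 50 CPM in the higher one. Predicted genes and mitochondrial genes were passed over in the rankings.

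Class shares were tested by Pearson's r and Spearman's rho with hours, each with a 2-sided permutation p over all 362880 orders of the 9 libraries and Benjamini-Hochberg adjustment over 11 classes. Their intervals are exact binomial (Clopper-Pearson) at 95%. For 0 cells the upper limit given is that of this interval. Comparisons of single libraries used CPM with exact Poisson intervals at 95% and no test. A fold with 0 counts in one library was taken against a floor of 3 counts. Lists were set against 10000 random lists matched on expression. Log2 ratios for lists and distances used a pseudocount of 1 CPM. The 36 h pair gave the size of difference expected between libraries of the same time.

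Scrublet with an expected rate of 0.05 called 25 of 35350 cells (0.0707%), far below that rate. Either its threshold missed doublets or they had been removed before deposit, which is not given in the sources used here. As an alternative chosen after this was seen, the 5% of cells with the highest scores (1762) were left out. For the clustering alternatives, 2000 variable genes, 30 principal components and 15 neighbours were used, and each Leiden cluster took the most frequent class of its cells. The class was unchanged for 69.6% of cells at 1 setting without cell cycle genes, 67.1% at the coarse resolution of 0.5 and 74.2% at the fine resolution of 2.

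The procedures were tested on simulated data before use. With a true log2 change of 1 over the time course, 33.2% of changed genes were found, and with 2, 84.5%, all with the right sign. For the quadratic model the values were 40.7% and 85.4%. False calls made up 3.95% to 10% of calls. Camera gave a p under 0.05 for 1 of 20 random lists. In these simulations genes varied independently and at most 199 tested genes changed, so the preset correlation was not put to the test. Simulated pairs of libraries held counting noise only, with 200 genes above 50 CPM changed 4-fold. Of these, 99.5% were among the 200 top-ranked genes, but real libraries differed by more than counting noise. For simulated shares 96.7% of moving classes were called and 0 of 220 unmoving ones.

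The alternatives tried were DESeq2's Wald test, limma-trend on the deposited log2 values, relative log expression (RLE) in place of TMM, no low-count filter, each library left out, the 36 h pair summed, 24 to 72 h only, a step after 72 h, the median UMI count as a covariate, cells with at least 2000 UMIs, cells without called doublets, fry in place of camera, other cluster settings, TMM-scaled CPM and a pseudocount of 5. After the data were seen, further ones were added: the highest doublet scores left out, cells under 15% mitochondrial counts, genes of at least 700 bases only, and hours on the log2 scale.

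Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.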

Results

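Single cells sorted from mouse small-intestinal organoids were seeded anew and sampled while they grew back, and messenger RNA was counted cell by cell. Organoids are epithelial cultures that hold the stem, absorptive and secretory cells of the intestinal lining, and these came from the duodenum of wild-type C57BL/6 mice. The series holds 10 libraries. The 0 h library is the maintenance culture, taken 6 days after passage in a commercial medium (IntestiCult). The other 9 cover 24 to 108 h after seeding in steps of 12 h, with 2 libraries at 36 h and 1 at each other time. Regrowth began in a medium of EGF, Noggin and R-spondin (ENR) with 25% Wnt3a-conditioned medium, 10 µM of the Rho-kinase inhibitor Y-27632 and, for the first 24 h, 3 µM of the Wnt activator CHIR99021. ENR alone was used from 72 h on.

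The deposited matrix held 35350 cells, 22135 genes and 11 cell classes assigned by the authors. The 0 h library had 4261 cells and a total count of 34081950. At 24 h there were 4549 cells with 41523434 counts. The first 36 h library gave 3115 cells with 21941306 counts and the second 2068 cells with 16400191, the smallest total of all. The deepest library, 48 h, reached 60227065 counts over 5103 cells. It was followed by 51985459 counts over 4568 cells at 60 h, 35709772 over 3193 at 72 h, 34599000 over 3317 at 84 h and 33198343 over 3179 at 96 h. The 108 h library was the smallest in cells, with 1997 and 21060618 counts. Median UMI counts per cell lay between 6709 in the first 36 h library and 9906 at 48 h. The median mitochondrial share was lowest at 24 h, at 6.44%, and highest at 108 h, at 10.3%.

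The 36 h pair was the only repeat of a time point, and the labels do not say whether its libraries came from separate cultures. Their counts differed by more than counting noise, with a chi-square per degree of freedom of 4.56 over 11424 genes, which does not show whether the cultures were separate. Both entered the tests below as libraries, and with the pair summed to 1 library 2835 genes rose and 2516 fell in place of 3138 and 2874. Among the 3428 genes above 50 CPM (a gene's counts scaled to a fixed library total) in the pair, 99% differed by less than 0.32 on the log2 scale. The p-values of single genes over time rest on the scatter of libraries about a fitted line, which may be technical. There were 9 such libraries over all cells and 7 or 9 within classes. Class shares were tested by permuting the libraries instead, and camera sets a list against the other genes.

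Regrowth began with cell classes that were almost missing from the starting culture. The class the authors named Reprogramming held 66.6% of cells at 24 h (3031 of 4549; 95% exact binomial interval 65.2 to 68.0%), 36.1% and 33.8% in the 36 h libraries, 12.1% at 48 h and 0.851% at 108 h, against 1 of 4261 cells at 0 h. The Regenerative class peaked at 36 h, at 42.0% and 41.7%, and was down to 3.29% at 84 h. No such cell was seen among 1997 at 108 h, which allows a share of up to 0.185%, or among 4261 at 0 h, which allows up to 0.0865%. Transit-amplifying (TA) and stem cell progenitors made up 2.70% at 24 h (interval 2.25 to 3.22%), 50.9% at 60 h and 39.0% at 108 h, compared with 68.2% at 0 h. Enterocyte progenitors made up 0.0879% at 24 h, 39.4% at 84 h and 3.30% at 108 h. Mature Enterocytes, the absorptive cells, made up 0.110% at 24 h and 46.1% at 108 h (interval 43.9 to 48.3%), compared with 17.9% at 0 h. These intervals cover counting error only, and shares of one library add up to the whole, so no class moves alone.

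Among the secretory classes, Exocrine cells held between 0.835% and 2.43% of cells up to 72 h and between 6.29% and 7.45% from 84 h on. Secretory progenitors were most frequent at 60 h, at 6.90% (interval 6.18 to 7.67%), and numbered 5 of 1997 cells at 108 h. Hormone-producing cells came and went. The class of endocrine cells other than enterochromaffin cells held 2.55% at 24 h, 1 cell in each 36 h library, 1.16% at 48 h, and no cell among 3193 at 72 h, which allows up to 0.115%. Enterochromaffin cells, the serotonin producers, and Tuft cells were at 0 in both 36 h libraries, with upper limits of 0.118% and 0.178%. Tuft cells numbered 57 in the whole series.

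Across the 9 libraries of 24 to 108 h, shares were tested against time for each of the 11 classes by exact permutation of the libraries (two-sided, 362880 orders), with Benjamini-Hochberg adjustment over the classes. A class counted as changed where both Pearson's r and Spearman's rho passed. The Enterocyte share rose (r = 0.880, permutation p = 5.5e-06, adjusted p = 6.1e-05; rho = 0.996, p = 1.1e-05, adjusted p = 6.1e-05; both raw values are the smallest the orders can give). Without the 24 and 108 h libraries its r was 0.862, and within the 6 libraries of 24 to 72 h it was 0.791. The Reprogramming share fell (r = -0.841, permutation p = 0.0023, adjusted p = 0.0094; rho = -0.996, p = 1.1e-05, adjusted p = 6.1e-05), with r = -0.877 without those 2 libraries and -0.913 within 24 to 72 h. The Regenerative share fell too (r = -0.879, permutation p = 0.0028, adjusted p = 0.0094; rho = -0.895, p = 0.0022, adjusted p = 0.0079). Its r was -0.965 without the 24 and 108 h libraries and -0.703 within 24 to 72 h, where the exact permutation p was 0.12. For Exocrine cells r passed (0.863, permutation p = 0.0034, adjusted p = 0.0094) and rho did not (0.745, p = 0.027, adjusted p = 0.073), and r within 24 to 72 h was 0.384. Exocrine cells passed both without the 24 h library (rho = 0.898), Enterochromaffin cells without 72 h (rho = 0.831) and Enterocyte progenitors without 108 h (rho = 0.922). The other classes did not pass. After 72 h there were only 3 libraries, too few for a value of their own.

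**Figure D1:**
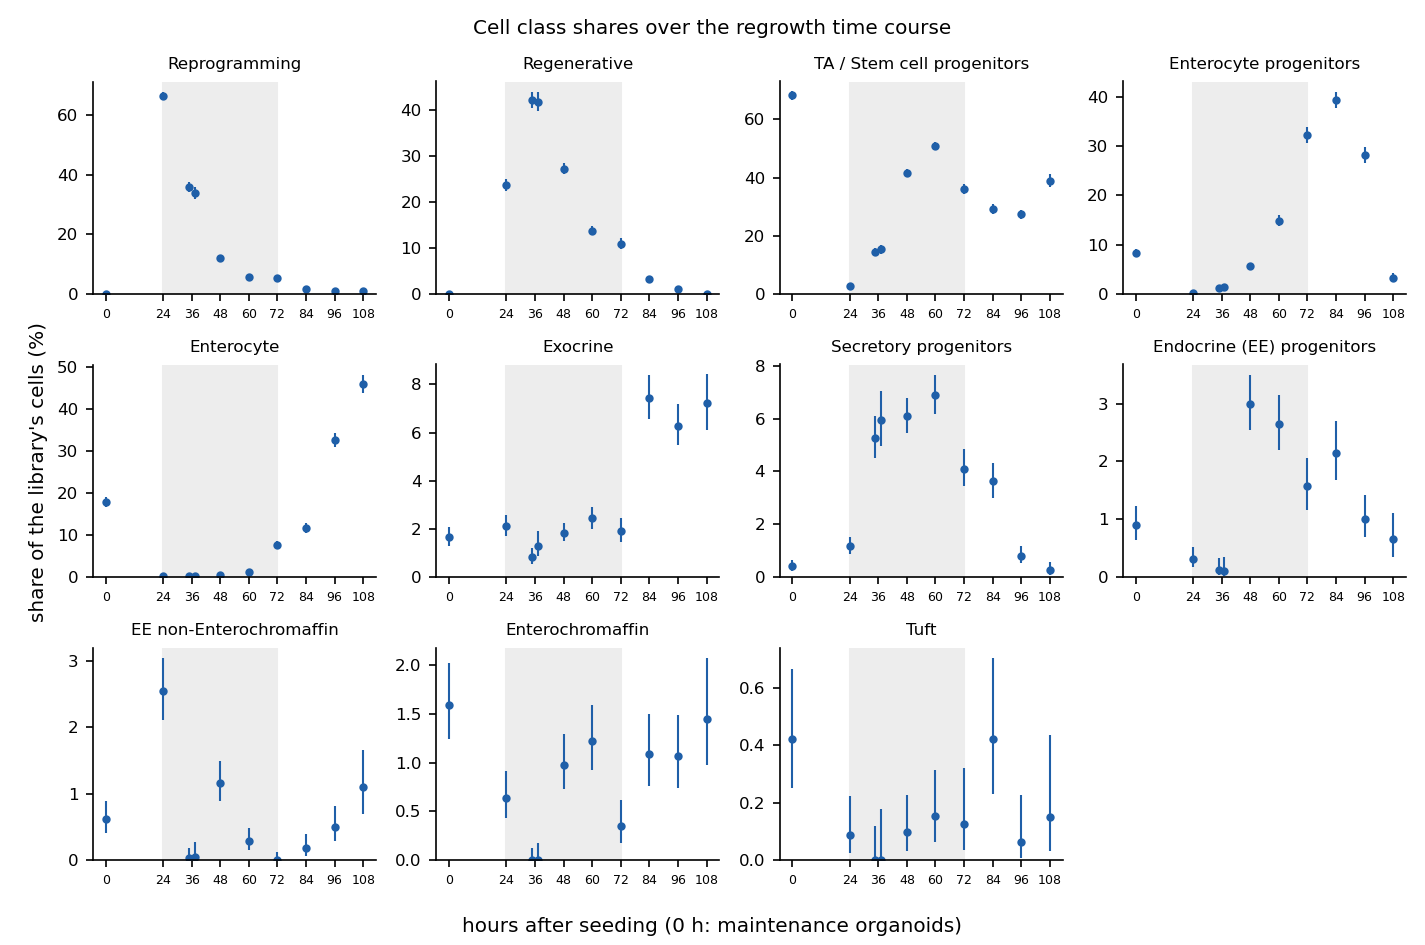
Share of each library's cells (%, vertical axis) in the 11 classes of the authors against hours after seeding (horizontal axis), 1 panel per class, with points for libraries and bars for 95% exact binomial intervals; the grey band marks 24 to 72 h, the medium with Wnt3a-conditioned medium and Y-27632. Reprogramming cells go from 66.6% at 24 h to 0.851% at 108 h while Enterocytes go from 0.110% to 46.1%.

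Which genes changed over regrowth was tested on counts summed over all cells of a library, with edgeR's quasi-likelihood test of a linear slope over 24 to 108 h. Of 12257 genes, 3138 rose and 2874 fell at a Benjamini-Hochberg adjusted p under 0.05. Changes are given as the fitted log2 difference from 24 to 108 h with its standard error (SE), over 9 libraries, and positions are those of GRCm38.

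The falling side was led by genes linked to epithelial injury and to foetal-type epithelium. S100a6 (chromosome 3, 90612882 to 90624181), a calcium-binding protein, fell by 5.14 ± 0.61 (adjusted p = 2.0e-04), from 1639 CPM at 24 h to 37.8 CPM at 108 h, close to the 33.0 CPM at 0 h. Lgals3 (chromosome 14, 47367751 to 47386160), which encodes galectin-3, fell by 4.71 ± 0.53 (adjusted p = 1.4e-04), from 866 to 40.2 CPM. The mesothelin gene Msln (chromosome 17, 25748613 to 25754378) fell by 4.71 ± 0.70, from 125 to 9.26 CPM, and the annexin gene Anxa1 by 3.41 ± 0.51, from 65.7 to 12.3 CPM. S100a11 fell by 3.66 ± 0.53. Hmgcs2, the rate-limiting enzyme of ketone body synthesis, fell by 3.54 ± 0.68, and by 5.50 without the 108 h library. The rest of the 10 genes with the steepest fall were Polr2l, a subunit of RNA polymerases (-4.24 ± 0.60), Atp5k (-3.79 ± 0.70) and Ndufb1-ps (-3.70 ± 0.60) of the respiratory chain, and the histone gene Hist1h2ap (-3.43 ± 0.85). S100a6, S100a11, Atp5k, Ndufb1-ps and Hist1h2ap have median annotated transcripts under 700 bases. In that length class 32.5% of 919 genes fell and 15.5% rose, and its median level at 108 h lay 0.26 below that at 24 h on the log2 scale.

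The steepest rises were those of Olfm4, several enzyme genes, Slc16a3 and Reg1. Olfm4 (chromosome 14, 79984081 to 80023139), a marker of intestinal stem cells, rose by 5.87 ± 0.69 (adjusted p = 1.9e-04), from 4.33 CPM at 24 h through 94.7 CPM at 60 h to 540 CPM at 108 h, against 390 CPM at 0 h. Fmo5, a flavin monooxygenase, rose by 6.16 ± 0.46 (adjusted p = 2.2e-05) and Ugt2b5, a glucuronosyltransferase, by 6.66 ± 0.64. The retinol and alcohol dehydrogenase genes Rdh7 and Adh1 rose by 6.19 ± 0.82 and 5.79 ± 0.61. Aoc1, which breaks down histamine and polyamines, rose by 5.32 ± 0.42, and Clec2h and AA467197 by 5.69 ± 0.69 and 5.23 ± 0.89. Slc16a3 (chromosome 11, 120948480 to 120960868), a lactate exporter, rose by 6.95 ± 1.43 (adjusted p = 0.0036), but stayed at 3.21 CPM or below up to 84 h and reached 81.5 CPM at 96 h and 93.1 CPM at 108 h. Reg1, a secreted lectin of the Reg family, rose by 6.86 ± 1.53 (adjusted p = 0.0053), from 43.5 to 2859 CPM, and without the 108 h library its adjusted p was 0.056. Without the 24 h library the change was 10.6 for Slc16a3 and 10.7 for Reg1. The median mitochondrial share of cells moved alongside, at 6.44% at 24 h, 8.49% at 96 h and 10.3% at 108 h.

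**Figure D2:**
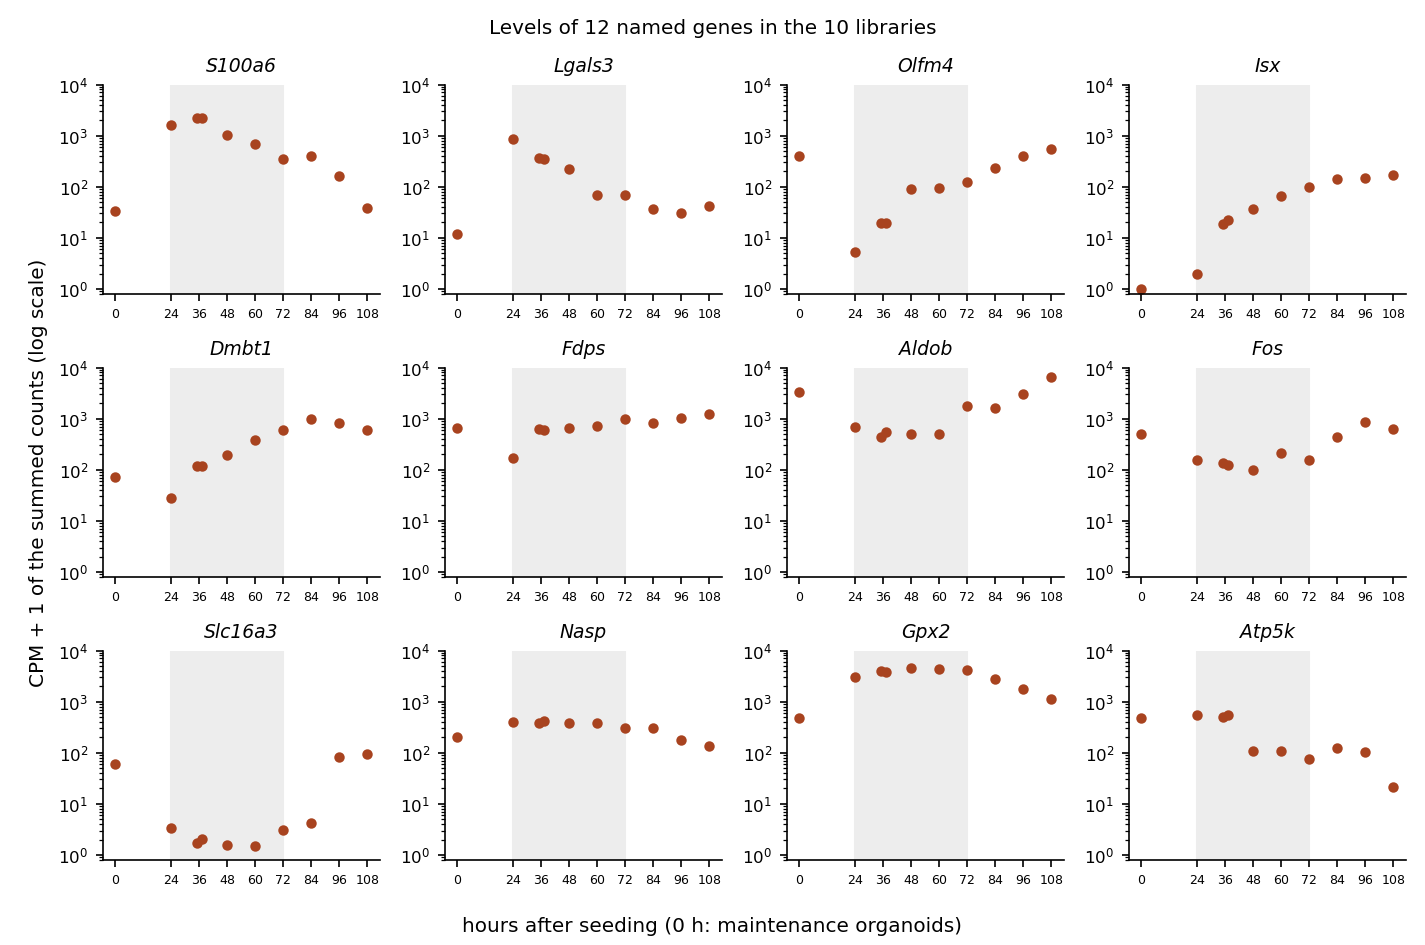
CPM of counts summed per library, plus 1, on a log axis (vertical) against hours after seeding (horizontal) for 12 genes, 1 panel each, with 1 point per library. S100a6 goes from 1639 CPM at 24 h to 37.8 at 108 h, while Olfm4 goes from 4.33 to 540.

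Of 36 gene lists fixed before the data were examined, along with the rule for the genes named here, 32 had enough measured members for a test. Limma's camera with a preset correlation, adjusted over the 32 lists by Benjamini-Hochberg, called 5 lists lower and 10 higher with time. None of the 15 calls held with an estimated correlation, where each of these lists had an adjusted p = 0.63.

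Genes of injured and foetal-type epithelium fell as a group. Of 19 measured members 14 fell and 0 rose, and 14 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.8e-06; adjusted p = 0.63 with an estimated correlation). Besides S100a6 they included the keratin gene Krt7 (-1.73 ± 0.25) and Areg, an EGF-receptor ligand (-2.31 ± 0.54; -3.55 without 108 h). Division genes fell as well. Of 42 S-phase genes 34 fell, 35 adjusted over the list alone (camera adjusted p = 3.3e-09), among them the histone chaperone gene Nasp (-1.46 ± 0.26). Of 52 genes of the G2 and M phases 41 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.3e-09). The tubulin gene Tubb4b changed by -0.96 ± 0.21. A list of 14 markers of cycling cells, which shares members with both, had 11 fallen and 0 risen, also adjusted over the list alone (camera adjusted p = 4.6e-04). Most of the drop in summed counts came after 72 h. The S-phase list held 0.411% of counts at 24 h, 0.393% at 72 h and 0.215% at 108 h. For the G2 and M list these values were 1.02%, 1.06% and 0.553%. Inside TA and stem cell progenitors 16 of 42 S-phase genes fell and 1 rose. Of 52 G2 and M genes 8 fell and 1 rose there, and of 14 cycling markers 2 fell and 0 rose. Among 15 measured Wnt target genes 10 fell and 0 rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 4.6e-04), with Sox9 at -0.90 ± 0.15 and the receptor gene Ephb2 at -0.84 ± 0.15. Each of these 4 lists had an adjusted p = 0.63 with an estimated correlation. Wnt activation by the medium went down along the same axis, with 3 µM CHIR99021 at 24 h only and Wnt3a-conditioned medium at 25% up to 72 h and 0 after it. Among the cycling genes Ube2c had -0.83 ± 0.28 and Birc5 -0.95 ± 0.33, and over 24 to 72 h alone their slopes were positive, at 0.35 and 0.11. Ube2c did not pass without 96 h (edgeR adjusted p = 0.079) or 108 h (0.15), nor Birc5 without 48 h (0.058), 96 h (0.076) or 108 h (0.14), with changes of -0.48 and -0.40 without 108 h.

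Absorptive genes rose by 108 h, but not steadily. Among 26 enterocyte markers 11 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.5e-04; adjusted p = 0.63 with an estimated correlation). The summed counts of the enterocyte list first fell, from 0.946% of counts at 24 h to 0.439% and 0.485% in the 36 h libraries and 0.373% at 60 h. They then reached 1.01% at 72 h and 1.79% at 108 h. Aldob, an enzyme of fructose use, rose by 3.44 ± 0.51, from 690 CPM at 24 h to 6606 CPM at 108 h, and the disaccharidase gene Sis by 3.71 ± 0.54. Of 12 transporter and enzyme genes of the middle of the villus 8 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 5.1e-05), such as the glucose carrier gene Slc5a1 (2.89 ± 0.36). Of 9 genes of the villus bottom 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0025). Lypd8, a secreted antibacterial protein, rose by 2.03 ± 0.32, while the glutathione peroxidase gene Gpx2 had a change of -1.40 ± 0.49 (edgeR adjusted p = 0.036) that did not pass without 36 h number 1 (0.059), 36 h number 2 (0.051), 48 h (0.058), 96 h (0.11) or 108 h (0.21; change -0.75). Both villus lists had an adjusted p = 0.63 with an estimated correlation. Fatty acid oxidation had 12 risen and 2 fallen members of 21, also adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.63 with an estimated correlation), with Acaa2 at 1.80 ± 0.34 and Acadm at 1.12 ± 0.16. That list was not called without the 108 h library (adjusted p = 0.18).

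Genes of oxygen shortage and sugar breakdown rose. Of 23 measured members 17 rose and 1 fell, or 19 and 2 adjusted over the list alone (camera adjusted p = 6.6e-05; adjusted p = 0.63 with an estimated correlation). Ldha, which makes lactate, rose by 1.23 ± 0.25, from 1536 to 3707 CPM. Immediate-early genes, which answer growth signals and stress within minutes, had 16 risen and 2 fallen members of 21, also adjusted over the list alone (camera adjusted p = 1.6e-06). Fos rose by 2.78 ± 0.48 and Ier2 by 1.92 ± 0.13. Cholesterol synthesis had 13 risen of 24 and 0 fallen, 14 adjusted over the list alone (camera adjusted p = 1.0e-04). Fdps, an enzyme of isoprenoid synthesis, rose by 1.70 ± 0.44 (1.12 without 24 h), with most of the step between 24 h (166 CPM) and 36 h (632 and 599 CPM), and Cyp51 by 1.31 ± 0.28. Among 18 genes of endoplasmic reticulum stress and secretion 8 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.012), such as Atf4 (0.93 ± 0.17) and Asns (1.27 ± 0.27), and the list was not called without the 24 h library (adjusted p = 0.063). These 3 lists had an adjusted p = 0.63 with an estimated correlation.

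Secretory markers rose in part. Of 14 goblet cell genes 9 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 2.6e-04), including Fcgbp, a mucus component (2.10 ± 0.29). Of 20 Paneth cell genes 9 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0043), with Itln1 at 2.88 ± 0.32 and the lysozyme gene Lyz1 at 1.84 ± 0.39. Both lists had an adjusted p = 0.63 with an estimated correlation. Their summed counts did not rise steadily but were highest at 84 h. The goblet list held 0.156% of counts at 24 h, 0.132% at 72 h, 0.387% at 84 h and 0.214% at 108 h. For the Paneth list these values were 0.156%, 0.0771%, 0.430% and 0.256%. Lyz1 had a negative slope, -0.35, over 24 to 72 h alone, and 13 of the Paneth genes have short transcripts.

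The other lists were not called. Among 17 stem cell genes 6 rose and 6 fell, 7 each adjusted over the list alone (camera adjusted p = 0.91), with Olfm4 and Smoc2 (0.90 ± 0.24) on the rising side; the list's median was -0.12 and its mean 0.36. Of 14 p53 target genes 3 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.079), among the latter Ccng1 (-1.63 ± 0.19). This list was called lower without the 108 h library (adjusted p = 0.0027) and over its 13 members of at least 700 bases (0.013). Of 9 tuft genes 5 rose, 7 adjusted over the list alone (camera adjusted p = 0.10), and the list was called without 24 h (0.031) or 96 h (0.046). Retinoid genes had 6 risen and 3 fallen of 12, also adjusted over the list alone (camera adjusted p = 0.17; 0.020 without 24 h), among them Isx, a transcription factor that represses vitamin A uptake (4.87 ± 0.97; 0.987 CPM at 24 h, 168 CPM at 108 h, 0 counts at 0 h). Risen and fallen members numbered 3 and 1 of 23 enteroendocrine genes (0 and 1 adjusted over the list alone), 3 and 0 of 10 secretory progenitor genes (2 and 0), 1 and 2 of 7 M-cell genes, 3 and 5 of 14 YAP targets, 5 and 1 of 12 Notch genes, 4 and 2 of 15 interferon genes, 1 and 2 of 4 genes of MHC class II, 3 and 0 of 9 villus-top genes (2 and 0), 4 and 0 of 11 brush-border genes, 7 and 6 of 17 genes of EGF ligands and feedback and 6 and 1 of 11 BMP genes, with the same counts adjusted over the list alone unless given. Their camera adjusted p ran from 0.15 for the villus top to 0.91 for M cells. Median and mean had opposite signs for the enteroendocrine (0.14 and -0.03, direction up), M-cell (-0.02 and 0.35, down), YAP (0.03 and -0.20, down) and immune lists (-0.04 and 0.17, up). Of cells that an epithelial culture should lack, 1 of 4 immune genes rose (Itgam, at most 0.902 CPM, not passing without 96 h, 0.063, or 108 h, 0.081), the only fibroblast gene measured, Pdgfrb, rose (at most 1.71 CPM), the only endothelial gene, Egfl7, did not pass (-0.47 ± 0.20), and no erythrocyte gene was measured. Of 13 mitochondrially encoded genes 3 rose and 3 fell, 2 and 3 adjusted over the list alone; their median was 0.23, their mean -0.28 and the camera direction down (adjusted p = 0.91). None of the 30 listed ribosomal protein genes was in the deposited table.

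**Figure D3:**
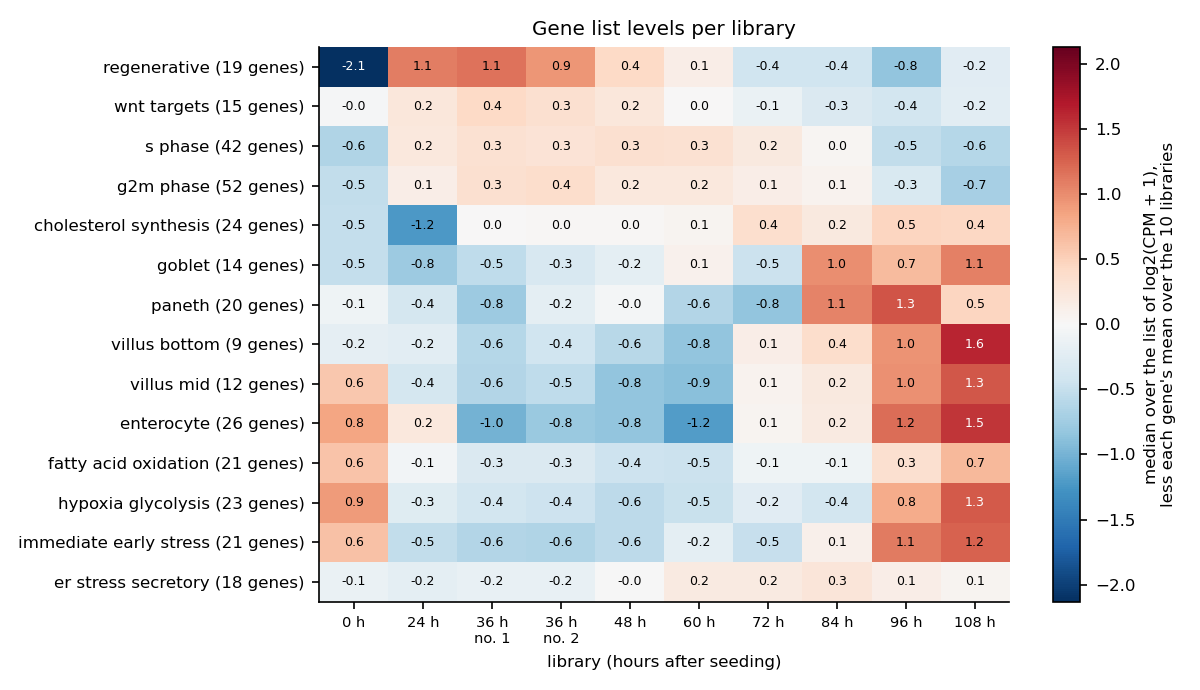
Heat map of 14 gene lists (vertical) over the 10 libraries (horizontal, by hours after seeding); colour gives the median over a list's genes of log2(CPM + 1) less the gene's mean over the 10 libraries. The list of injured and foetal-type epithelium is high at 24 and 36 h and low at 0 h, and the immediate-early and hypoxia lists are high at 0, 96 and 108 h.

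Some genes were highest or lowest in the middle of regrowth. A quadratic term of time, tested by the same edgeR test, gave 1256 genes higher and 974 lower at 66 h than the mean of 24 and 108 h. Dmbt1, a mucosal defence glycoprotein (chromosome 7, 131032053 to 131121630), stood out on the high side at 1.96 ± 0.23 on the log2 scale (adjusted p = 0.0021), with 26.9 CPM at 24 h, 1003 CPM at 84 h and 604 CPM at 108 h. The other 7 genes with the largest value were Lsm5 (1.65 ± 0.39), Lbhd1, Hspe1, Selenoh, Cks2, Lsm3 and Spata24 (1.35 ± 0.16). Of these, Lsm5, Selenoh, Cks2, Lsm3 and Spata24 have transcripts under 700 bases, and their level was lowest at 108 h. Hspe1 did not pass without 60 h (adjusted p = 0.073) or 108 h (0.071), nor Lsm5 without 60 h (0.057). Without 108 h the values were 0.77 for Lsm5, 0.69 for Hspe1, 0.91 for Selenoh, 0.88 for Cks2 and 0.84 for Lsm3. On the low side Ctrb1, a digestive protease, lay at -6.19 ± 1.09 (edgeR adjusted p = 0.013; 33.6 CPM at 24 h, 0.308 CPM at 60 h and 275 CPM at 108 h). The lipid carrier gene Apoa4 had -3.28 ± 0.56, the keratin gene Krt20 -2.60 ± 0.46 and the peptidase gene Anpep -2.48 ± 0.34. The hypoxia genes Bnip3 (-3.44 ± 0.72) and Ndrg1 (-2.28 ± 0.51), Selenop (-2.45 ± 0.49) and Slc16a3 (-4.22 ± 1.15) also dipped. Without 24 h the adjusted p was 0.058 for Ctrb1, 0.063 for Apoa4, 0.051 for Krt20, 0.092 for Bnip3, 0.060 for Ndrg1, 0.11 for Selenop and 0.32 for Slc16a3. Bnip3 (0.071), Ndrg1 (0.073), Selenop (0.055) and Slc16a3 (0.13) did not pass without 60 h either, nor Ndrg1 without 72 h (0.0505) or 84 h (0.053), Selenop without 108 h (0.096), nor Slc16a3 without 36 h number 1 (0.073) or 2 (0.071), 48 h (0.096), 72 h (0.094) or 84 h (0.088). The number of genes higher midway was 488 without 108 h, 502 without 60 h and 807 without 84 h, and the number lower midway 450 without 60 h.

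The medium changed within this time course. CHIR99021 was present only up to 24 h, and Wnt3a-conditioned medium and Y-27632 up to 72 h, so slopes were fitted again up to 72 h. This range still spans the removal of CHIR99021, which falls together with the 24 h library. Over the 6 libraries of 24 to 72 h 333 genes rose and 487 fell, and 5225 of the 5954 genes called over all times that could be tested had the same sign. Of these 687 passed again. Isx (8.00, expressed per 84 h), Olfm4 (8.15), Dmbt1 (6.89), S100a6 (-4.87) and Lgals3 (-6.66) had slopes of the same sign as over all times. From the first 36 h library to 72 h, in 1 medium, Isx stood at 18.0 and 99.4 CPM, Olfm4 at 18.5 and 121 CPM, Dmbt1 at 116 and 588 CPM, S100a6 at 2211 and 343 CPM, and Lgals3 at 367 and 68.5 CPM. With a step after 72 h added to the slope, 218 genes rose and 223 fell, and 5880 of the 6012 genes kept their sign. Medium and time cannot be told apart for changes from 24 to 36 h or after 72 h.

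Changes inside cell classes were tested for the 5 classes with at least 50 cells in 7 or more libraries, on counts summed per library and class. All changes are per 84 h, also in the Regenerative, Reprogramming and Secretory progenitor classes, which were followed from 24 to 84 h only. Among TA and stem cell progenitors, in 9 libraries, 1758 genes rose and 1483 fell by edgeR's test. Olfm4 rose by 5.07 ± 0.37 inside this class (adjusted p = 2.3e-05; 48 CPM at 24 h, 1186 CPM at 108 h), the zinc transporter gene Slc39a5 by 4.41 ± 0.19, Dmbt1 by 4.16 ± 0.69 and the hypoxia genes Ankrd37 and Bnip3 by 5.48 ± 0.77 and 5.28 ± 1.46. S100a6 (-4.53 ± 0.78), Lgals3 (-4.43 ± 1.05), Hmgcs2 (-4.72 ± 0.50), the trefoil gene Tff3 (233 to 18.2 CPM) and the glutathione transferase gene Gsta1 (-4.82 ± 0.36) fell. At 24 h S100a6 stood at 649 CPM in this class and 1639 CPM over all cells, and Lgals3 at 230 and 866 CPM. Background RNA from other cells is therefore not excluded for the fall of S100a6 and Lgals3 here. Without the 108 h library 951 genes rose and 854 fell in this class.

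In Regenerative cells 589 genes rose and 568 fell over 7 libraries. Isx rose by 5.85 ± 1.24 (edgeR adjusted p = 0.044; 1.58 CPM at 24 h, 129 CPM at 84 h) and Dmbt1 by 5.51 ± 0.91, followed by the protease gene Prss32, the actin-capping gene Capg and Slc39a5. Skeletal actin Acta1 (-6.79 ± 0.97), Hmgcs2 (-6.40 ± 0.60), Agr3, Ndufb1-ps and Lgals3 (-4.58 ± 0.90) fell. Lgals3 stood at 483 CPM in this class at 24 h and 866 CPM over all cells, so background RNA is not excluded for it. The number of risen genes was 362 without 24 h and 378 without 84 h. In Reprogramming cells 643 genes rose and 633 fell over 7 libraries. Isx (7.79 ± 1.64), Mxd4, a MAX-binding repressor (5.33 ± 0.43), Dmbt1 (4.91 ± 0.68), Prss32 and Ddit4l rose, while Hmgcs2 (-6.71 ± 0.48), the metallothionein gene Mt2 (-5.18 ± 0.38), Pet100, Ndufb1-ps and Krt20 (-3.61 ± 0.72) fell. Without 24 h these counts were 335 and 321, and fallen genes numbered 389 without 60 h and 398 without 72 h. This class had 3031 cells at 24 h and 53 at 84 h. At 84 h Dmbt1 stood at 806 CPM in Regenerative and 492 CPM in Reprogramming cells, below its level over all cells. Background RNA is thus not excluded for its rise in these 2 classes.

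In Secretory progenitors 146 genes rose and 200 fell over 7 libraries. Dmbt1 (5.71 ± 0.35), the defensin gene Defa30 (5.08 ± 0.87), Isx (4.80 ± 0.40), Olfm4 and Rep15 rose, and Msln (-9.61 ± 1.08), Lgals3 (-7.83 ± 1.06), Acta1, Ly6a (-6.35 ± 0.70) and Sprr2a3 fell. At 24 h Msln stood at 70.9 CPM and Lgals3 at 222 CPM in this class, against 125 and 866 CPM over all cells. Ly6a was higher in the class (238 against 195 CPM). Background RNA is not excluded for the fall of Msln and Lgals3. Nor is it for the rise of Dmbt1, which at 84 h stood at 635 CPM in this class, below its level over all cells. Risen genes numbered 63 without 36 h number 1, 70 without number 2 and 92 without 72 h, and fallen genes 116 and 112 without either 36 h library. In Exocrine cells, over 7 libraries of 24 to 108 h, 410 genes rose and 311 fell. Mptx1, a pentraxin of Paneth cells (8.85 ± 1.22), Sis (8.42 ± 1.11), Fmo5 (7.65 ± 0.82), Arg2 and Hsd17b13 rose. At 108 h Sis stood at 247 CPM in this class and 1205 CPM over all cells, and Fmo5, Arg2 and Hsd17b13 were likewise lower in the class, so background RNA from other cells, which was not estimated, is not excluded for these 4 genes. Mptx1 was higher in the class (264 against 13.2 CPM). Psca (-8.74 ± 0.75), S100a6 (-6.10 ± 0.40; 4835 CPM at 24 h, 70.0 CPM at 108 h), Tppp3, Atp5k and Polr2l fell. The count of risen genes was 228 without 48 h, 268 without 60 h, 181 without 96 h and 222 without 108 h, and that of fallen genes 123 without 48 h, 183 without 60 h and 126 without 96 h.

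How the maintenance culture and early regrowth differed was read from the 0 h and 24 h libraries, which also differ in medium. There was 1 library each, so folds carry intervals for counting error only and no test. Among genes higher at 0 h, Nupr1, a stress-induced regulator (chromosome 7, 126623249 to 126630861), stood at 778 CPM against 7.86 CPM, 99-fold higher (88.9 to 111). Olfm4 was 89.7-fold higher (77.6 to 105), alpha-fetoprotein Afp 47.3-fold, Pbld1 38.7-fold, Reg1 26.3-fold, Slc16a3 24.8-fold, Aldoc 22.7-fold, Rdh7 21.9-fold, and the metallothionein genes Mt2 and Mt1 22.4-fold and 16.3-fold. Mt1 alone reached 25474 CPM at 0 h. Genes of injured epithelium were lower at 0 h. Msln had 0 counts at 0 h and was at least 1421-fold lower, against a floor of 3 counts per library. Anxa1 was 299-fold lower (142 to 649), Clu, a clusterin gene that marks revival stem cells, 264-fold (128 to 658), Lgals3 80.7-fold, Ly6a, also called Sca1, 67.8-fold, Plaur 51.0-fold and S100a6 49.7-fold. The remaining genes were Sult6b2 (42.3-fold), Mboat1 (39.6-fold) and Akr1b8 (33.5-fold). The 36 h pair differed by at most 0.52 on the log2 scale in these genes, except Afp at -1.29.

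As groups, the 19 genes of injured and foetal-type epithelium had a median log2 ratio of -3.11 between 0 h and 24 h, below all of 10000 random lists of the same size matched on expression. S-phase genes lay at -0.91 and G2 and M genes at -0.64, likewise below all random lists. Immediate-early genes (1.53), enterocyte genes (1.13), hypoxia genes (1.13), enteroendocrine genes (0.79), fatty acid oxidation (0.68) and cholesterol synthesis (0.65) were above all of them. The enteroendocrine list was mixed, with 10 members more than 1 unit higher at 0 h and 5 more than 1 unit lower, and 8 hormone genes summed to 1462 CPM at 0 h and 2381 CPM at 24 h. Stem cell genes had a median of 0.36, with 6 of 17 more than 1 unit higher at 0 h. Percentiles describe these libraries alone. The lists that rose from 24 to 108 h thus included several that stood higher in the starting culture.

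How near the culture came to its start was read from the 108 h and 0 h libraries, 1 each and in different media. Enterocytes made up 46.1% of cells at 108 h and 17.9% at 0 h. Among genes higher at 108 h, Isx had 0 counts at 0 h and was at least 1910-fold higher, against the floor of 3 counts. Clca1, a goblet cell protease, was 153-fold higher (91.1 to 281), Prss32 60-fold, Capg 59.3-fold, Fmo5 42.8-fold, the brush-border protease gene Mep1b 34.8-fold, Sult6b2 31.9-fold, Adh6a 25.8-fold, Papss2 25.1-fold and Adh4 20.7-fold. Mt2 and Mt1 were 237-fold (218 to 260) and 142-fold (138 to 147) lower, Afp 30.8-fold and the disulfide isomerase gene Pdia2 21-fold. Hist1h2ap, Atp5k, Sec61g, Atp5md, Ndufb1-ps and Ndufa3 were between 17.2-fold and 23.5-fold lower; of these, all but Sec61g have transcripts under 700 bases, as have Mt1 and Mt2. Genes of injured and foetal-type epithelium lay above 0 h, with a median log2 ratio of 2.07 and 14 of 19 members more than 1 unit higher. Their summed counts moved less, at 0.0783% of counts at 108 h and 0.0525% at 0 h. Goblet (1.43), M-cell (1.28), villus-bottom (1.22), cholesterol (1.03), enterocyte (0.99), villus-mid (0.96), retinoid (0.91) and Paneth genes (0.64) also lay above all random lists. Among these, summed counts also moved less for the goblet list (0.214% of counts at 108 h, 0.209% at 0 h), the M-cell list (0.0352% and 0.0247%) and the enterocyte list (1.79% and 1.65%). They were lower at 108 h for the Paneth list (0.256% and 0.286%). Enteroendocrine genes (-0.64) and G2 and M genes (-0.19) had medians below all random lists, and stem cell genes (-0.27) below all but 0.290%.

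The step from 0 h to 24 h was the largest between neighbouring times, with a root mean square log2 CPM difference of 0.81 over 12257 genes, against 0.16 within the 36 h pair. It spans 24 h, reseeding and a change of medium, while each later step spans 12 h. The steps from 24 to 36 h measured 0.35 and 0.36 with either 36 h library, and those from 36 to 48 h 0.33 and 0.32. The smallest step, from 48 to 60 h, was 0.20. Later steps were 0.34 from 60 to 72 h, 0.34 from 72 to 84 h across the change of medium, 0.37 from 84 to 96 h and 0.43 from 96 to 108 h. The distance to 0 h was largest at 36 h, at 0.87 for both libraries, and smallest at 96 h, at 0.67; at 108 h it was 0.76. Spearman's rho with 0 h, across genes, which are not independent replicates, was likewise highest at 96 h (0.958) and stood at 0.948 at 108 h. Genes with transcripts under 700 bases, whose median was lowest at 108 h, enter these values. How far they carry the difference between 96 and 108 h was not tested.

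**Figure D4:**
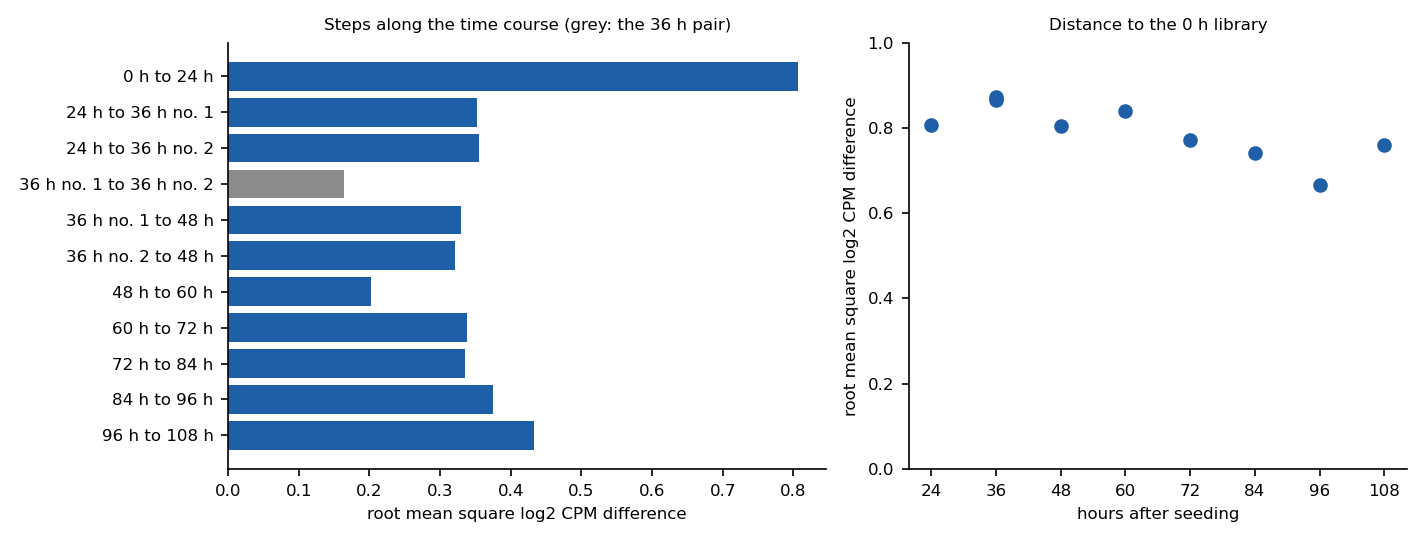
Root mean square log2 CPM difference over 12257 genes. Horizontal bars give each step between neighbouring times, with the difference on the horizontal axis and the 36 h pair in grey. Points give the distance of each library to 0 h (vertical axis) against hours after seeding (horizontal axis). The step from 0 to 24 h, which spans 24 h and a change of medium, is the largest, at 0.81. The later steps span 12 h each, and 96 h is nearest to 0 h, at 0.67.

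**Figure D5:**
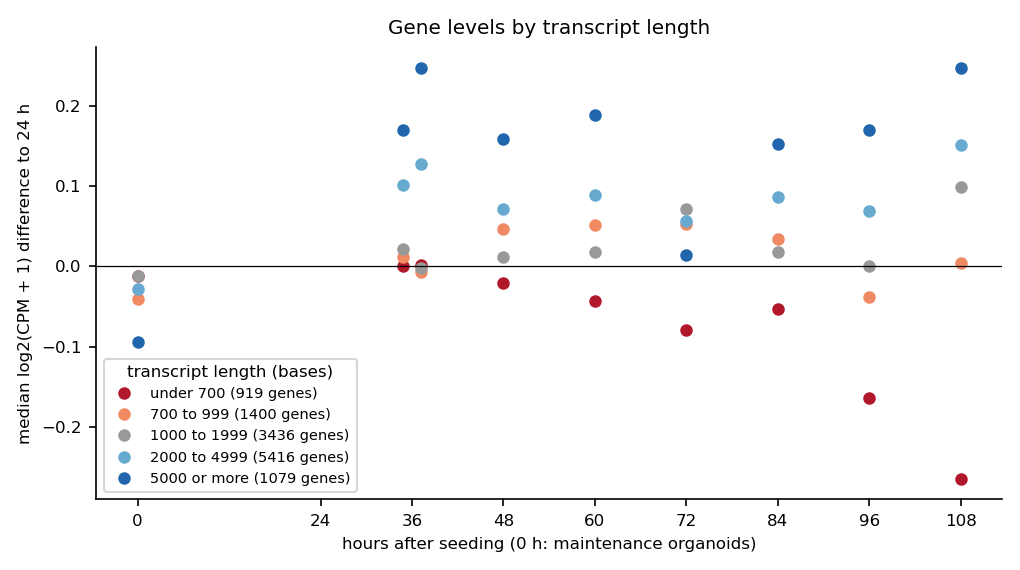
Median log2(CPM + 1) difference to the 24 h library (vertical axis) of genes grouped by median annotated transcript length (colours of the points) against hours after seeding (horizontal axis). The group under 700 bases ends at -0.26 at 108 h, while the group from 5000 bases up ends at 0.25.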

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

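The slope differences in this part were not among the planned comparisons, and the genes to name were picked by size after the values were seen. Some slopes inside cell classes differed from those inside TA and stem cell progenitors, as an interaction term in edgeR's test. This raised 203 genes for Exocrine cells (67 steeper upward, 136 downward), 58 for Regenerative cells (32 and 26), 609 for Reprogramming cells (273 and 336) and 22 for Secretory progenitors (4 and 18). Among Exocrine cells Reg1 had a slope difference of 9.07 (adjusted p = 9.5e-04), S100g 4.23 and the defensin gene Defa3 -4.89. Ly6a (3.59), Gsta1 (2.48) and S100a6 (1.81) declined less in Regenerative cells than in TA and stem cell progenitors, whereas the stem cell regulator gene Ascl2 differed by -1.73. For Reprogramming cells the differences were 6.70 for Msln, 6.08 for Ly6a, 6.05 for Clu and 3.98 for Anxa1. For Secretory progenitors Anxa3 differed by -2.81 and S100a6 by -2.46. Between 24 and 84 h Reprogramming cells went from 3031 to 53 and Regenerative cells from 1074 to 109, so cells left in these classes may be a selected part of them, while Exocrine cells went from 96 to 247 and Secretory progenitors from 53 to 120. Whether selection or the assignment of cells to classes accounts for the 609 genes was not tested, and background RNA was not estimated.

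The fall of genes with short transcripts was weighed against 3 explanations by tests written down before their values were computed, apart from the values over all short genes, which were added later. From 84 to 108 h all 919 such genes had a median of -0.24 over all cells against 0.06 for genes of 1000 bases or more, and of -0.07 against 0.14 in Enterocytes, -0.33 against -0.01 in Enterocyte progenitors, -0.16 against 0.13 in Exocrine cells and -0.13 against 0.12 in TA and stem cell progenitors. A loss of short transcripts from every cell alike, in library making or counting, stays open, as does lower expression in every class: the 299 fallen genes fell in each class by at least 0.679 of their change over all cells, but they had been chosen for falling. A shift in class shares did not account for all of it. The 268 of these genes measured inside TA and stem cell progenitors had a median change of -1.12 there. Over all cells the 299 had -1.43, a ratio of 0.781. A part from shares stays open, as all 919 short genes had -0.13 in that class against -0.24 over all cells. Lower expression of the respiratory chain as a whole did not account for the fall either. Its 19 members of 1000 bases or more had a median of 0.55 and its 43 short members -1.46, a ratio of -0.377.

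The late rise of hypoxia and immediate-early genes was weighed by tests of which those on enterocytes and on the medium were written after the rise was seen. Inside TA and stem cell progenitors the risen members had 1.05 of the median change over all cells (2.25 against 2.13), so a larger share of Enterocytes did not account for all of it. These members had been chosen for rising over all cells, so a part from shares stays open. Of the median rise from 72 to 108 h, 17.8% was reached at 84 h, 12 h after the change of medium, but this rests on 1 library, so a response to the medium stays open. How far the 108 h library carries the calls stays open, as 60.6% of the 33 members still passed without it; the median rise was 1.55 from 72 to 96 h and 1.70 from 72 to 108 h. The median mitochondrial share was highest in the libraries where these lists were high, at 8.93% at 0 h, 8.49% at 96 h and 10.3% at 108 h. Whether cell quality or handling contributed was not tested. Crowding and size of late organoids could not be tested with these libraries.

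The gap in endocrine cells at 36 h was weighed by tests of which that on class borders was written after it was seen. Summed over all cells, 8 hormone genes reached 2381 CPM at 24 h, 46.6 and 135 CPM in the 36 h libraries, 1336 CPM at 48 h and 14.5 CPM at 72 h. The higher 36 h library had 0.0566 of the 24 h level, so borders drawn between classes did not account for the gap. Carry-over of endocrine cells from the seeded culture was left open. The hormone profile at 24 h had r = 0.819 with 0 h and 0.843 with 48 h, a difference of -0.0239 across 8 genes, which are not independent replicates.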

How the results depend on the processing

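Over 310 results and 31 alternatives, 2758 of 3240 values stayed the same, 319 were weaker, 19 stronger, 122 moved and 22 reversed. Fits on 24 to 72 h alone, or with a step after 72 h, changed most: 333 genes rose and 487 fell in the former, and 218 and 223 in the latter, against 3138 and 2874. Of 110 named genes 27 passed in the former, 64 did not and 19 changed sign. These 19, expressed per 84 h, were Birc5 (0.109), Creb3l3 (-0.720), Dll4 (-0.207), Gmnn (0.168), Gpx2 (0.689), Id1 (-0.202), Jund (-0.472), Lyz1 (-0.348), Myo1a (-0.222), Pcna (0.0134), Pgk1 (-0.0440), Plac8 (-0.151), Slc12a2 (0.278), Slc16a3 (-0.590), Slc7a9 (-0.308), Tap1 (-0.0433), Ube2c (0.353), Ush1c (-0.0705) and mt-Co3 (-0.100). With the step, Creb3l3 (-0.130), Lyz1 (-0.00800) and Slc12a2 (0.0780) changed sign. The cause was not tested. DESeq2 kept 108 of the 110 named genes, limma-trend 103, RLE 110 and the UMI covariate 99. With each library left out, 895 of 984 values of named genes still passed. Over these runs risen genes numbered 2257 to 3157 and fallen ones 2000 to 3089, genes higher midway 488 to 1179 and lower midway 450 to 1040. Within classes the ranges for risen and fallen genes were 181 to 442 and 123 to 358 (Exocrine), 362 to 569 and 401 to 570 (Regenerative), 335 to 629 and 321 to 588 (Reprogramming), 63 to 118 and 112 to 223 (Secretory progenitors), and 951 to 1903 and 854 to 1541 (TA and stem cell progenitors). Without a low-count filter 227 genes rose in Secretory progenitors. Called lists numbered 9 to 11 higher and 5 to 6 lower with each library left out, 0 and 0 with an estimated correlation, and 16 higher with fry. Classes that rose numbered 1 to 2 with each library left out, and 2 with Leiden resolution 2, with cells under 15% mitochondrial counts and without cell cycle genes among the features. Classes that fell numbered 2 throughout the libraries left out. With a pseudocount of 5 the step from 0 h to 24 h was 0.622. That pseudocount moved 25 of 52 values of the comparison of 0 h with 24 h and 27 of 52 of that of 108 h with 0 h, and TMM scaling 3 and 22. Genes of at least 700 bases alone gave 2796 risen and 2830 fallen. The planned run on all barcodes equals the one reported, since no cell was removed. No paired analysis was possible because only 36 h has 2 libraries and the labels pair no libraries across times.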

Other observations

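Within classes, gene lists moved apart, and these tests were added after the values were seen. The marker genes behind the class names are not given, so list members may have helped to assign cells to classes. Slopes of such genes within any class, and their differences between classes, may then partly be set by class membership. This was not tested. In Reprogramming cells, 13 of 14 p53 target genes rose and 0 fell (camera adjusted p = 1.5e-17; adjusted p = 0.089 with an estimated correlation), with 9 to 12 risen as libraries were left out, 9 of them without 24 h. Trp53inp1 rose by 4.76 ± 0.46, the pro-apoptotic gene Bbc3 by 3.48 ± 0.37, Mdm2 by 1.97 ± 0.27 and the cell cycle inhibitor gene Cdkn1a by 1.46 ± 0.39. In TA and stem cell progenitors 4 of 14 fell, among them Bax (-0.85 ± 0.17) and Ccng1 (-1.23 ± 0.23), and 1 rose, and the list was not called (camera adjusted p = 0.10; adjusted p = 0.57 with an estimated correlation). The difference of slopes between these classes held for the p53 list with an estimated correlation (10 of 14 genes steeper upward; adjusted p = 0.041), for genes of injured and foetal-type epithelium (8 of 19 steeper upward; 0.0039), for cycling markers (11 of 14 steeper downward; 0.041), for enteroendocrine genes (5 of 13 steeper downward; 0.047) and for EGF ligands and feedback (2 of 16 steeper upward; 0.047). Between Regenerative cells and TA and stem cell progenitors it held for the injury list (5 of 18 steeper upward; 0.020) and the enteroendocrine list (7 of 15 steeper downward; 0.020). For both enteroendocrine results background RNA is not excluded, as hormone genes over all cells went from 2381 CPM at 24 h to 14.5 CPM at 72 h. Nor is background RNA excluded for the injury list. Its member S100a6 stood at 649 CPM in TA and stem cell progenitors at 24 h and 1639 CPM over all cells. Reprogramming cells lost division genes, with 23 of 42 S-phase genes fallen (camera adjusted p = 4.6e-15; 0.089 with an estimated correlation), but 9 without 24 h. Of the 19 genes of injured and foetal-type epithelium 5 rose and 0 fell in these cells (camera adjusted p = 5.1e-05; adjusted p = 0.30 with an estimated correlation), with 3 to 7 risen as libraries were left out, 3 of them without 24 h. These cells numbered 53 at 84 h.

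In Regenerative cells, of 13 Wnt targets 9 fell and 0 rose (camera adjusted p = 1.3e-14; adjusted p = 0.078 with an estimated correlation), with Lgr5 at -3.44 ± 0.45, Ascl2 at -3.04 ± 0.40 and Axin2 at -2.03 ± 0.26. Against TA and stem cell progenitors the Wnt list was steeper downward with the preset correlation (1 of 14 genes; camera adjusted p = 9.1e-07), which did not hold (adjusted p = 0.16 with an estimated correlation). Of 16 stem cell genes 8 fell and 1 rose (camera adjusted p = 3.2e-06; adjusted p = 0.078 with an estimated correlation). Of 7 secretory progenitor genes 5 fell, among them Atoh1 (-4.52 ± 0.90) and Neurog3 (-4.45 ± 0.84) (camera adjusted p = 9.4e-08; adjusted p = 0.078 with an estimated correlation). Cholesterol synthesis had 11 of 24 genes risen, 6 without 72 h, with Insig1 at 2.52 ± 0.30 (camera adjusted p = 1.3e-14; adjusted p = 0.31 with an estimated correlation). In Secretory progenitors 8 of 14 genes of injured and foetal-type epithelium fell (camera adjusted p = 1.5e-39; adjusted p = 0.051 with an estimated correlation), such as Anxa1 (-6.49 ± 0.69) and Areg (-5.47 ± 0.42). Background RNA is not excluded here either, as the member Msln stood at 70.9 CPM in this class at 24 h and 125 CPM over all cells. Inside TA and stem cell progenitors 16 of 21 immediate-early genes rose, with Fosb at 4.63 ± 0.85 and Egr1 at 3.43 ± 0.58, and 15 of 22 hypoxia genes (7 without 108 h), with Car9 at 2.45 ± 0.22. The camera calls of these 2 lists did not hold with an estimated correlation (adjusted p = 0.43 and 0.57).

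The number of genes with a slope stood apart from other orders of the times. Of 100 orders, including the real one, 1 had as many as the real 6012 genes; the highest other had 2859. For the quadratic term 2 of 100 orders had as many as the real 2217 genes, and the highest other had 4690. The real count is 2217 here and not 2230 because all orders were run on the genes kept for the linear fit. In the order with 4690 genes the quadratic term had a correlation of -0.771 with the real hours. It may in part take up the linear trend. Yet an order with -0.773 gave 0 genes, one with 0.774 gave 2 and one with 0.827 gave 6, so the reason was not settled. Genes named for the quadratic term should be read with their CPM at each time.

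The starting culture differed from the regrown one in medium as well as in time, so the 142-fold lower Mt1 and the 0 counts of Isx at 0 h cannot be given to regrowth. Medium, time and library are joined at 24 h and at 108 h. Replicate libraries at 24, 72, 96 and 108 h, and cultures kept in the earlier medium past 72 h, would help at late times; at 0 and 24 h the medium itself would have to be varied.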
